A study of Mus musculus with 8 samples.

How the data were processed

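RNA was sequenced from 8 mouse CD4 T cell populations, with 1 library per population. Per the labels' protocols, naive cells (CD44-negative, high in CD62L) and memory cells (high in CD44, CD62L-negative) were sorted from lymph nodes of wild-type mice, and their RNA was taken directly. The other 6 populations came from naive cells cultured with antibodies against CD3 and CD28. Th0 cultures received antibodies blocking IL-4 and interferon gamma, plus IL-2. Th1 cultures received anti-IL-4, IL-12 and IL-2, and Th2 cultures received anti-interferon gamma, IL-4 and IL-2. Th9 cultures received anti-interferon gamma, IL-4 and TGF-beta. Th17 cultures received both blocking antibodies with IL-6, IL-23 and TGF-beta, and Treg cultures received both blocking antibodies with TGF-beta and IL-2. Th1, Th2, Th9, Th17 and Treg cells were then sorted on a reporter of Ifng, Il4, Il9, Il17 or Foxp3, while the labels name no such sort for Th0. Polarizing condition and reporter sort therefore changed together in each comparison with Th0. The labels name both wild-type and reporter mice for these 5 populations, so whether the mouse line changed too is not settled. They name an Il17 reporter without saying which gene, and Il17a was taken for it here. Poly(A) RNA was extracted with a QIAGEN RNeasy Micro or a Zymo Direct-zol kit, per the labels' protocols, which do not say which kit served which library. Libraries were made with an Illumina TruSeq mRNA kit and sequenced with paired reads on a HiSeq2500 instrument, and strand use is not given in the sources used here.

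The authors deposited a table of FPKM values, fragment numbers scaled to transcript length and library size, with 1 value per locus and population, and a gene annotation on build GRCm38. CASAVA 1.8, FastQC, TopHat2, Bowtie2 and Cufflinks are named in the submitters' processing notes, with the builds GRCm38 and mm10. Which tool made the table, the versions of the last 4, any scaling between libraries and any filter are not given in the sources used here. FPKM values are not counts, so no count model was fitted. Some genes that every cell uses were listed at exactly 0 in 1 or more libraries, so a 0 was read only as a listed 0.

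The table held 66077 loci. Locus names were matched to the deposited annotation by symbol and overlapping position, and 1015 further names were matched through RefSeq synonyms (assembly GRCm38) of a present symbol. Of the loci, 21209 were protein-coding, 7552 long noncoding, 5614 pseudogenes, 4170 small RNAs and 468 immune receptor segments. A further 16291 had a name with no match and 10773 had no name, and neither class entered a comparison. Where a gene had several loci, the locus with the highest mean was kept, which left 7475 long noncoding loci and, outside the mitochondrial genome, 20406 protein-coding loci. Of the coding loci kept before that exclusion, 523 joined several protein-coding genes and gave 1 value for all of them. Of the long noncoding loci, 3660 overlapped a protein-coding gene, and with strand use unknown the reads of such partners cannot be told apart.

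Depth was read from the FPKM values themselves. In 5330 loci with a single transcript over 800 bases, low values fell on multiples of the value of 1 fragment. Between 72.4% and 81.4% of low values lay within 0.05 steps of a whole multiple up to 5, so the estimates are approximate. They gave about 3130000 fragments for naive, 69300000 for memory, 145000000 for Th0, 123000000 for Th1, 104000000 for Th2, 120000000 for Th9, 118000000 for Th17 and 115000000 for Treg. For a 2 kb transcript at 5 FPKM this is 28.7 fragments in naive, a relative counting error of 18.7%, against 1330 fragments and 2.74% in Th0. At 2 kb, 3 fragments correspond to 0.523 FPKM in naive and at most 0.0235 FPKM in the other 7 libraries. These errors cover counting only.

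Differences were computed as log2(FPKM + 1), which understates differences of low genes. A protein-coding gene was counted as higher or lower when FPKM + 1 differed at least 4-fold and the higher library had at least 5 FPKM. For a long noncoding gene this minimum was 1 FPKM. A 4-fold difference of FPKM + 1 already demands more than 1 FPKM in the higher library, so the minimum for long noncoding genes decided no call. With 1 library per population there was no test, p-value or standard deviation in any of the 7 comparisons. The 25 gene lists covered T cell identity, naive and quiescence genes, memory and effector phenotype, follicular helper, Th1, Th2, Th9, Th17 and Treg genes, TGF-beta response, interferon response, cell cycle, glycolysis, cholesterol synthesis, immediate early genes, inhibitory receptors, cytotoxic granules and known long noncoding RNAs. They also held markers of B cells, CD8 T and NK cells, gamma-delta T cells, myeloid cells, mast cells and basophils, erythroid cells and platelets, and stroma and endothelium. The median difference of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list outside percentiles 2.5 to 97.5 is described as standing apart in these libraries. Lat, Irf8, Plk1, Aldoa, Nr4a1, Trdc, Trgc1, Flt3, Tsix, Snhg1, Ifng-as1, Mir155hg, Norad and Lockd had no locus matched to the name and were not analysed under these names. A locus of theirs under another symbol would have been missed by their lists, so they are not shown to be unmeasured. Some further genes are not reported here.

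Named genes followed a rule. Per comparison it took the 8 protein-coding genes with the largest positive and the 8 with the largest negative difference, and 4 long noncoding genes each way. Per population it took the 5 protein-coding and 3 long noncoding genes with the largest ratio to the next library. From each list it took as examples up to 4 members with the largest difference among those of at least 1 FPKM. The text gives a selection of these. A population-specific gene had at least 5 FPKM and FPKM + 1 at least 4 times that of the next library. The comparisons, lists, rule and most alternatives were fixed before the data were examined. Chosen after seeing the data were the same ranking restricted to loci above 0 in both libraries, the summary of similarity as a median over pairs, and 5 alternatives. These left out loci listed at 0 (in the comparisons and in the population-specific genes), thinned the deeper library to the naive depth, left out transcripts under 300 bases, or used only the 6 cultured libraries for neighbouring genes.

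The alternative settings were a pseudocount of 0.1 or 5 FPKM, other FPKM minimums, rescaling by the median of ratios or the upper quartile, the median of the other 5 cultured libraries in place of Th0, and other distances between neighbouring genes. A count was taken as kept when it stayed within 1.5 times its main value. A median or correlation was taken as kept when it stayed inside the 95% range of 200 Poisson redraws of the fragments, or, for neighbouring genes, within the half-width of the random range. Median-of-ratios factors ran from 0.909 in memory to 1.06 in Th0. The calculations were tested on simulated libraries with 200 planted genes per comparison. In the simulated Th0 against naive comparison on 20406 loci, 100% of 8-fold and 22% of 4-fold plants were called, and 1 unchanged locus. In the simulated Th1 against Th0 comparison on 20406 loci, 98% of 8-fold and 4% of 4-fold plants were called, and 0 unchanged loci. The simulated libraries differed only by the planted folds and Poisson counting error. Variation between animals, cultures, sorts or preparations was not simulated, so the calls of unchanged loci say nothing about it. Planted folds shrink under the added pseudocount, so true 4-fold differences fall short of the 4-fold rule. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.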

Results

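The data set held 8 RNA-seq libraries of mouse CD4 T cells, 1 per population, and was made to find RNAs, noncoding ones in particular, that differ between naive and effector cells. Naive and memory cells were sorted directly from lymph nodes, and Th0, Th1, Th2, Th9, Th17 and Treg cells were grown from naive cells, as described above. The naive library rested on about 3130000 fragments and the other 7 on 69300000 to 145000000, as estimated from the FPKM values. No population had a replicate, so none of the differences below has a replicate check, and each describes these libraries only. Coordinates are on GRCm38 from the deposited annotation and span the whole gene, and values cover all exons of a locus.

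Each reporter gene, with Il17a taken for the Il17 reporter, was highest in the library sorted on it. The sort selected for these genes, so this checks the labels only, and each gene also counts as a member of its population's list below. Ifng (ENSMUSG00000055170, chromosome 10, 118441047 to 118445892), the main Th1 cytokine, was at 243 FPKM in Th1, 235 in memory, 7.19 in Th0, 1.54 in naive and at most 0.559 in the others. Il4 (ENSMUSG00000000869, chromosome 11, 53602982 to 53618669) was at 142 FPKM in Th2, 116 in memory and 24.6 in Th9. Il9 (ENSMUSG00000021538, chromosome 13, 56479277 to 56482246) was at 53.6 FPKM in Th9 and 20.2 in Th2, and was listed at 0 in naive, memory, Th1 and Treg. Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) was at 35.1 FPKM in Th17 and 8.15 in memory. Foxp3 (ENSMUSG00000039521, chromosome X, 7579676 to 7595243), the transcription factor of regulatory T cells, was at 47.2 FPKM in Treg, 13.5 in memory and 4.19 in Th0. The transcription factor Tbx21 was at 62.3 FPKM in Th1, 42.9 in memory, 31.6 in Th9 and 12.3 in Th0. The locus of Gata3, which also holds 9230102O04Rik, was at 144 FPKM in Th2, 77.2 in Th9 and 1.29 in Th1.

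**Figure D1:**
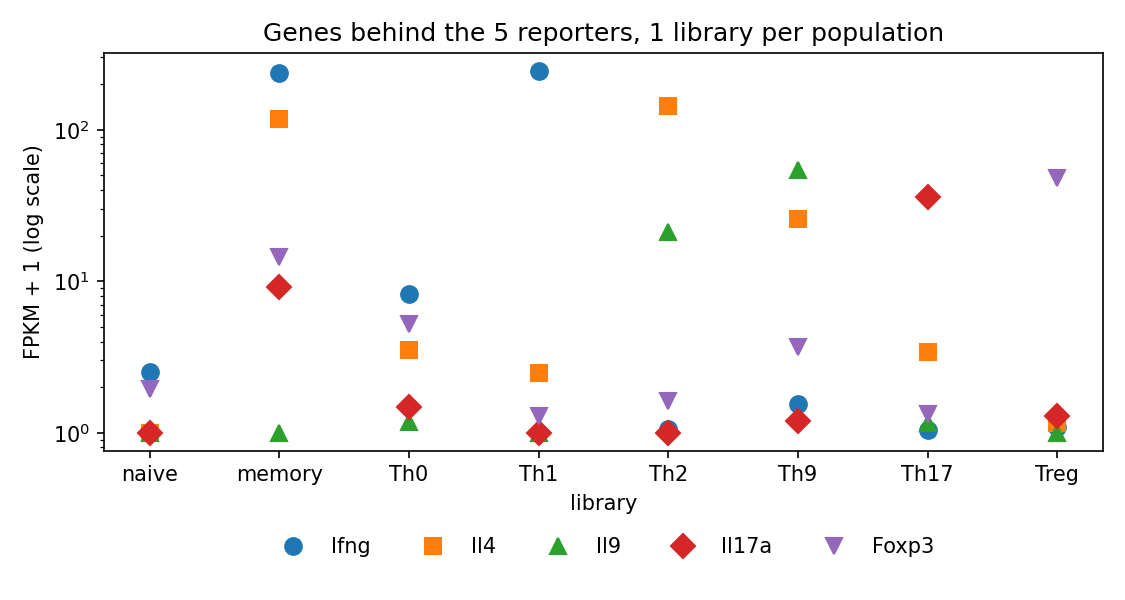
FPKM + 1 on a log axis for the 5 genes of the reporters, with Il17a taken for the Il17 reporter, in each of the 8 libraries, 1 point per gene and library. Each gene is highest in the library sorted on its reporter, and Ifng (235 FPKM) and Il4 (116 FPKM) are also high in memory.

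Across 20406 protein-coding loci, Th2 and Th9 were the most alike pair of libraries (Pearson r of log2(FPKM + 1) across genes, 0.989), followed by Th0 and Treg (0.986). Naive and memory had r = 0.965, and naive and Th2 were the least alike (0.901). The median over the 28 pairs was 0.957. Genes are not independent replicates, so these values carry no p-value.

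**Figure D2:**
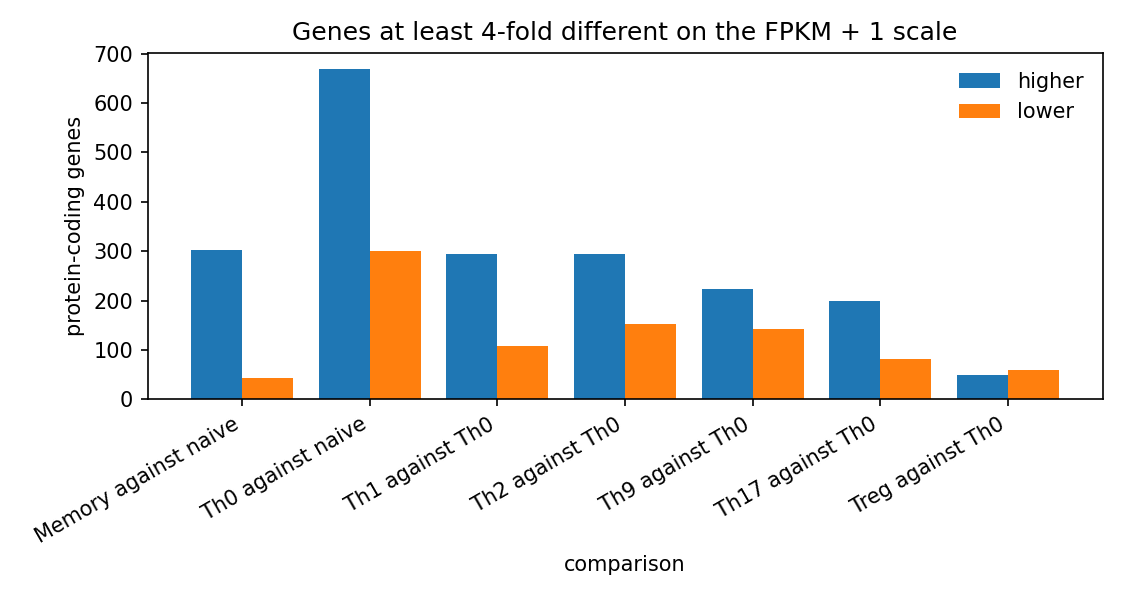
Number of protein-coding genes (vertical axis) at least 4-fold higher or lower on the FPKM + 1 scale in each of the 7 comparisons (horizontal axis), 1 library against 1. Th0 against naive has the most, 668 higher and 301 lower, and Treg against Th0 the fewest, 49 and 59.

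Memory against naive compared antigen-experienced with unprimed cells sorted from the same tissue. All 20 genes of the memory and effector phenotype list were higher in memory, 15 of them at least 4-fold, with a median log2 difference of 2.79 (percentile 100). The calcium-binding protein genes S100a4 (284 against 7.70 FPKM) and S100a6 (115 against 2.31) and Il2rb, a receptor chain for IL-2 and IL-15 (215 against 8.88), were among them. Of 17 naive and quiescence genes 16 were lower, 4 at least 4-fold (median -0.92, percentile 0), such as Igfbp4 (10.9 against 415 FPKM) and Dapl1 (6.31 against 119). The chemokine receptor gene Ccr9 was the exception, at 63.0 against 2.30 FPKM. Genes of plasmacytoid dendritic cells were also high in memory, as described below, so which cells gave this Ccr9 signal is not settled. Lists of several effector fates were also higher in memory.

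The Th1 list had 11 of 15 members at least 4-fold higher (median 2.77, percentile 100), including Ccl5 (296 against 5.85 FPKM) and Cxcr3 (51.3 against 0.409). The Treg list had 10 of 16 (median 2.75, percentile 100), with Tigit at 107 against 7.63 FPKM, and the Th17 list 7 of 14 (median 2.28, percentile 100), with Maf at 51.2 against 1.74. All 11 follicular helper genes were higher, 5 of them at least 4-fold (median 1.95, percentile 100), among them Tox2 (22.9 against 0.259 FPKM) and Cxcr5 (27.5 against 1.67). All 8 inhibitory receptors were higher (median 2.82, percentile 100), for instance Pdcd1 (60.9 against 2.54 FPKM) and Lag3 (32.0 against 1.57). The Th2 list (median 0.75, percentile 99.95), the Th9 list (1.02, percentile 99.87), the TGF-beta response (1.23, percentile 100), cytotoxic granules (1.45, percentile 100, 5 of 8 genes higher), immediate early genes (1.20, percentile 100), cell cycle (0.91, percentile 100) and glycolysis (0.29, percentile 97.94) also stood apart. T cell identity genes did not (median -0.09, percentile 54.19), nor did the interferon response (0.07, percentile 53.54) or cholesterol synthesis (0.19, percentile 90.38).

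Markers of other cell types also differed. The myeloid list was higher in memory (median 1.02, percentile 99.98), with Siglech at 89.6 against 0.961 FPKM and Tyrobp at 122 against 13.7. The antigen-presentation gene H2-Aa, also of this list, was at 241 against 30.9 FPKM. The CD8 T and NK list was also higher (median 0.91, percentile 99.66), with Klrb1c at 7.31 FPKM and listed at 0 in naive. The gamma-delta T cell markers Tcrg-C1 and Tcrg-C2 were at 21.5 and 11.9 FPKM in memory and at 1.82 and 0.948 in naive, and too few coding members were measured for a median. B cell, stroma and endothelium, mast cell and basophil, and erythroid lists did not stand apart, with medians of 0.41, 0.04, 0 and 0.11. The erythroid list had a mean of -0.01, opposite in sign to its median.

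In all, 302 protein-coding genes were at least 4-fold higher in memory and 43 lower, among 7871 with at least 5 FPKM in either library. Of the higher ones, 27 were listed at 0 in naive, where the low depth allows a transcript of 2 kb up to 0.523 FPKM by 3 fragments. The counts were 116 and 10 with a pseudocount of 5 FPKM. The autophagy kinase gene Pink1, among the largest negative differences, was at 43.3 against 922 FPKM.

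Th0 against naive compared activated cells without polarizing cytokines with resting cells. Cell division and metabolic genes were higher in Th0. Of 21 cell cycle genes all were higher, 17 at least 4-fold (median 3.87, percentile 100), including Cdk1 (133 against 0.604 FPKM) and the proliferation marker Mki67 (136 against 1.02). Of 12 glycolysis genes 11 were at least 4-fold higher (median 2.70, percentile 100), such as Tpi1 (762 against 20.9 FPKM) and Pgk1 (1114 against 79.2). Of 15 cholesterol synthesis genes 8 were (median 2.03, percentile 100), for instance Hmgcs1 (131 against 19.4 FPKM).

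The Treg list was higher (median 2.48, percentile 100), led by the IL-2 receptor alpha chain Il2ra (302 against 1.13 FPKM) and Tnfrsf4 (482 against 13.6). The memory and effector list (1.89, percentile 100), the Th1 list (1.36, percentile 99.95), inhibitory receptors (1.60, percentile 99.95) and cytotoxic granules (1.08, percentile 97.90) stood apart in the same direction, with the cytotoxic protease Gzmb at 213 against 0.511 FPKM. Lower lists were the naive and quiescence genes (median -1.42, percentile 0), with 6 of 17 at least 4-fold lower, among them Il7r (7.75 against 131 FPKM). Of 11 immediate early genes 7 were at least 4-fold lower (median -2.72, percentile 0), such as Fos (4.98 against 293 FPKM) and Junb (217 against 1775). The interferon response (-1.50, percentile 0), with Usp18 at 1.57 against 35.6 FPKM, and the TGF-beta response (-0.66, percentile 0.65), with Smad7 at 8.01 against 157 FPKM, were lower too. Among other cells' markers the myeloid list (-1.69, percentile 0), the erythroid and platelet list (-1.67, percentile 0) and the B cell list (-0.65, percentile 1.22) were lower in Th0, with C1qb at 13.2 FPKM in naive and listed at 0 in Th0, and Hbb-bs at 0.0178 against 13.4. The CD8 T and NK list had a median of 0.11 and a mean of -0.02.

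There were 668 protein-coding genes at least 4-fold higher in Th0 and 301 lower, among 8336. The neuritin gene Nrn1 (497 against 0.660 FPKM) and Igfbp7 (229 against 0.335) led the higher ones, and Dtx1, a Notch pathway gene (0.799 against 91.8), and Vipr1 (0.298 against 65.5) the lower ones. Eef1a1, which encodes a translation elongation factor, was listed at 0 in Th0 and each other cultured library, at 11027 FPKM in naive and 6110 in memory. Of the higher genes, 78 were listed at 0 in naive. Rescaling by the median of ratios shifted log2 differences in this comparison by -0.16 for highly expressed genes, and by less for low ones under the added pseudocount. The counts were 296 and 146 with a pseudocount of 5 FPKM.

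In Th1 against Th0 the Th1 list was higher and the cell cycle list lower. Of 15 Th1 genes 9 were at least 4-fold higher (median 2.80, percentile 100), including the IL-12 receptor chain Il12rb2 (326 against 4.30 FPKM), Ccl5 (800 against 15.1) and Ccl3 (375 against 13.6). The cytotoxic granule list was higher (1.82, percentile 100), with Gzmb at 1792 against 213 FPKM and Nkg7 at 469 against 50.3. All 21 cell cycle genes were lower, 1 of them at least 4-fold (median -1.43, percentile 0), for instance Tyms (20.2 against 86.0 FPKM).

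The memory and effector list was higher (1.47, percentile 100), as were immediate early genes (1.11, percentile 100), the Th17 list (0.97, percentile 99.99), the Th9 list (0.71, percentile 99.37, 5 of 8 genes higher) and the TGF-beta response (0.50, percentile 98.26). Inhibitory receptors had a median of 0.50 (percentile 97.97) but were split, with 4 genes higher and 4 lower, among them Cd160 at least 4-fold lower. Th17 list members high in Th1 included Il21 (115 against 0.302 FPKM), Maf (87.5 against 0.461) and Il23r (12.6 against 0.181). Cholesterol synthesis was lower (-0.46, percentile 1.32), with Idi1 at 31.7 against 111 FPKM. Glycolysis had a median of 0.71 (percentile 99.71) and a mean of -0.22, with Gapdh listed at 0 in Th1 and at 3403 FPKM in Th0. The follicular helper, B cell, and CD8 T and NK lists also differed in sign between median (-0.29, -0.21 and -0.09) and mean (0.21, 0.39 and 0.26), and none of these 3 stood apart.

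In Th1, 294 protein-coding genes were at least 4-fold higher and 108 lower, among 8395. Plac8 (602 against 5.56 FPKM), Ly6g (95.8 against 0.0952) and Serpinf1 (526 against 5.95) were among the largest positive differences, and Pdzk1ip1 (0.170 against 61.4), Nrgn (0.645 against 64.1) and Dlk1 (0.0966 against 34.8) among the largest negative ones above 0 in both libraries. Gapdh and Eef2 were listed at 0 in Th1. Against the median of the other 5 cultured libraries the counts were 128 and 33, and with a pseudocount of 5 FPKM 143 and 40.

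Th2 against Th0 showed the Th2 genes higher and the Th1 genes lower. Of 14 Th2 genes 9 were at least 4-fold higher (median 2.51, percentile 100), including Il24 (159 against 0.560 FPKM), Epas1 (93.5 against 0.653) and Il4 (142 against 2.5), the gene of the sort reporter. Of 15 Th1 genes 14 were lower, 7 at least 4-fold (median -1.87, percentile 0), such as Fasl (0.713 against 15.0 FPKM), Eomes (0.0197 against 5.92) and Ifng (0.0633 against 7.19). The cytotoxic granule list was lower (-1.91, percentile 0), with Gzmc at 0.804 against 30.5 FPKM, although Gzma was at 57.3 against 4.32.

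The Th9 list was higher (1.63, percentile 100), with Il10 at 106 against 1.17 FPKM and Basp1 at 185 against 15.0. The memory and effector list (1.12, percentile 100), glycolysis (0.47, percentile 98.21) and immediate early genes (0.49, percentile 99.42) were higher, with the transcription factor gene Prdm1, of the memory and effector list, at 13.6 against 0.352 FPKM. The Treg list was split, with a median of 0.51 (percentile 99.47), a mean of 0.15, 9 genes higher and 7 lower. Its lower members included Nt5e (1.23 against 49.8 FPKM), Lrrc32 (2.36 against 19.9) and Foxp3 (0.624 against 4.19). Cell cycle (-0.98, percentile 0), cholesterol synthesis (-0.61, percentile 0.22) and the interferon response (-0.53, percentile 0.66) were lower, for instance Gbp2 (44.7 against 228 FPKM). The mast cell and basophil list had a median of -0.02 (percentile 0.61), with no member at 1 FPKM in either library. Median and mean differed in sign for the follicular helper list (-0.25 and 0.20) and inhibitory receptors (-0.09 and 0.09).

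In Th2, 294 protein-coding genes were at least 4-fold higher and 153 lower, among 8399. Tnfrsf8, which encodes CD30 (290 against 2.54 FPKM), and Pth, the parathyroid hormone gene (84.9 against 0.0622), were among the largest positive differences. Ms4a4b (0.155 against 226) and the chemokine gene Xcl1 (0.254 against 59.0) were among the largest negative ones. The counts were 148 and 59 against the median of the other 5 cultured libraries, and 152 and 53 with a pseudocount of 5 FPKM.

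Th9 against Th0 gave differences in many of the genes named for Th2. Of 14 Th2 genes 6 were at least 4-fold higher (median 1.66, percentile 100), including Il24 (145 against 0.560 FPKM) and Il13 (146 against 10.5). Of 8 Th9 genes 3 were (median 1.28, percentile 100), Il9 (53.6 against 0.184 FPKM), Basp1 (289 against 15.0) and Il10 (12.2 against 1.17). Il9 is the gene of the sort reporter. The Th17 list (0.91, percentile 100), with Maf at 39.4 against 0.461 FPKM and Ahr at 13.3 against 1.24, and the TGF-beta response (0.70, percentile 99.93), with Pmepa1 at 80.3 against 21.2 FPKM, were higher as well.

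Cell cycle (median -1.05, percentile 0), naive and quiescence genes (-0.52, percentile 0.22), the Th1 list (-0.56, percentile 0.43) and T cell identity (-0.38, percentile 1.53) were lower, for instance Ccr7 (145 against 732 FPKM) and Cd3e (96.0 against 210). Of the 15 Th1 genes 11 were lower, while Il12rb2 (64.6 against 4.30 FPKM) and Tbx21 (31.6 against 12.3) were among the higher ones. Glycolysis had a median of 0.47 (percentile 99.47) and a mean of -0.52, with Gapdh listed at 0 in Th9. The mast cell and basophil list again stood apart at -0.02 (percentile 0.47) with no member at 1 FPKM, and the B cell list had a median of -0.07 and a mean of 0.36.

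In Th9, 224 protein-coding genes were at least 4-fold higher and 142 lower, among 8360. Timp1, an inhibitor of metalloproteinases (187 against 0.677 FPKM), and the retinol transporter gene Stra6 (145 against 1.47) were among the largest positive differences. Grik3 was at 581 FPKM in Th9 and listed at 0 in the other 7 libraries, and since exact zeros in this table also occur at genes every cell uses, this difference is uncertain. Eef2 was listed at 0 in Th9. The counts were 89 and 44 against the median of the other 5 cultured libraries, and 93 and 49 with a pseudocount of 5 FPKM.

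Th17 against Th0 was led by the Th17 list, with 11 of 14 members at least 4-fold higher (median 2.93, percentile 100). Il17f was at 268 against 0.328 FPKM, Il21 at 108 against 0.302, Maf at 81.2 against 0.461 and the chemokine gene Ccl20 at 43.7 against 0.282. The Th1 list was lower (-0.76, percentile 0.01, 12 of 15 genes lower), with Ifng at 0.0406 against 7.19 FPKM and Tbx21 at 2.46 against 12.3. Its member Il12rb2 was higher, at 34.7 against 4.30 FPKM. Cytotoxic granules (-1.37, percentile 0) and inhibitory receptors (-0.71, percentile 0.10) were lower too, for instance Cd160 (0.283 against 8.34 FPKM).

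All 12 glycolysis genes (median 0.69, percentile 99.92), the memory and effector list (0.70, percentile 100), immediate early genes (0.91, percentile 99.99) and the TGF-beta response (0.76, percentile 99.92) were higher, among them the glucose transporter gene Slc2a3 (479 against 164 FPKM) and Fos (52.9 against 4.98). All 21 cell cycle genes were lower (-0.72, percentile 0). The interferon response was lower (-0.36, percentile 1.51, 9 of 15 genes lower), with Irf1 at 30.9 against 125 FPKM, but its median was 0.04 over members of at least 1 FPKM. The mast cell and basophil list stood at -0.02 (percentile 0.67) with no member at 1 FPKM. Median and mean differed in sign for follicular helper (-0.27 and 0.63), Th9 (-0.08 and 0.19), known long noncoding RNAs (-0.07 and 0.04), cholesterol synthesis (-0.14 and 0.0020) and B cell genes (-0.26 and 0.09), none of which stood apart.

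In Th17, 200 protein-coding genes were at least 4-fold higher and 82 lower, among 8347. Upp1, a uridine phosphorylase gene (144 against 1.43 FPKM), and Gja1, which encodes a gap junction protein (110 against 1.82), were among the largest positive differences. Tnfsf10, which encodes the death ligand TRAIL (1.14 against 50.4), was among the largest negative ones. The counts were 59 and 33 against the median of the other 5 cultured libraries, and 85 and 29 with a pseudocount of 5 FPKM.

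Treg against Th0 had the fewest 4-fold differences of the 7 comparisons. All 10 TGF-beta response genes were higher (median 1.30, percentile 100), none at least 4-fold under the rule, such as Tgif1 (122 against 32.8 FPKM), Ldlrad4 (19.2 against 5.14) and Smad7 (26.3 against 8.01). All 12 glycolysis genes were lower (-1.14, percentile 0), for instance Slc2a3 (5.14 against 164 FPKM) and Slc2a1 (20.9 against 77.4). Of 16 Treg list genes 2 were at least 4-fold higher, Foxp3 (47.2 against 4.19 FPKM) and Nt5e, which encodes the ectonucleotidase CD73 (314 against 49.8). Foxp3 is the gene of the sort reporter. The list as a whole did not stand apart (0.08, percentile 95.51).

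The Th17 list was higher (0.69, percentile 100) with 9 of 14 members higher and 6 at least 4-fold higher, including Ccl20 (23.8 against 0.282 FPKM), Maf (18.5 against 0.461) and Ccr6 (60.7 against 8.96). Immediate early genes (1.03, percentile 100) and naive and quiescence genes (0.27, percentile 99.97, 11 of 17 higher) were higher, for instance S1pr1 (48.9 against 26.2 FPKM). The Th1 list was split, with a median of -0.43 (percentile 0.10), 7 genes higher and 8 lower, and Il18r1 at 39.3 against 8.12 FPKM. The Th2 list (-0.48, percentile 0.03, 9 of 14 genes lower), cytotoxic granules (-0.73, percentile 0.03), cholesterol synthesis (-0.63, percentile 0) and cell cycle (-0.35, percentile 0.05) were lower, with Gzmb at 24.9 against 213 FPKM. The interferon response had a median of -0.05 and a mean of 0.06.

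In Treg, 49 protein-coding genes were at least 4-fold higher and 59 lower, among 8133. Mid1 (41.6 against 0.628 FPKM) and Ctsw, a cathepsin gene (45.4 against 2.16), were among the largest positive differences. Tgm2, a transglutaminase gene (0.527 against 28.0), and Stc2 (1.32 against 34.7) were among the largest negative ones. Against the median of the other 5 cultured libraries the counts were 85 and 185, more than the 59 and 33 of Th17. The small number of differences in Treg thus depends on Th0 as the reference. With a pseudocount of 5 FPKM the counts were 16 and 19.

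**Figure D3:**
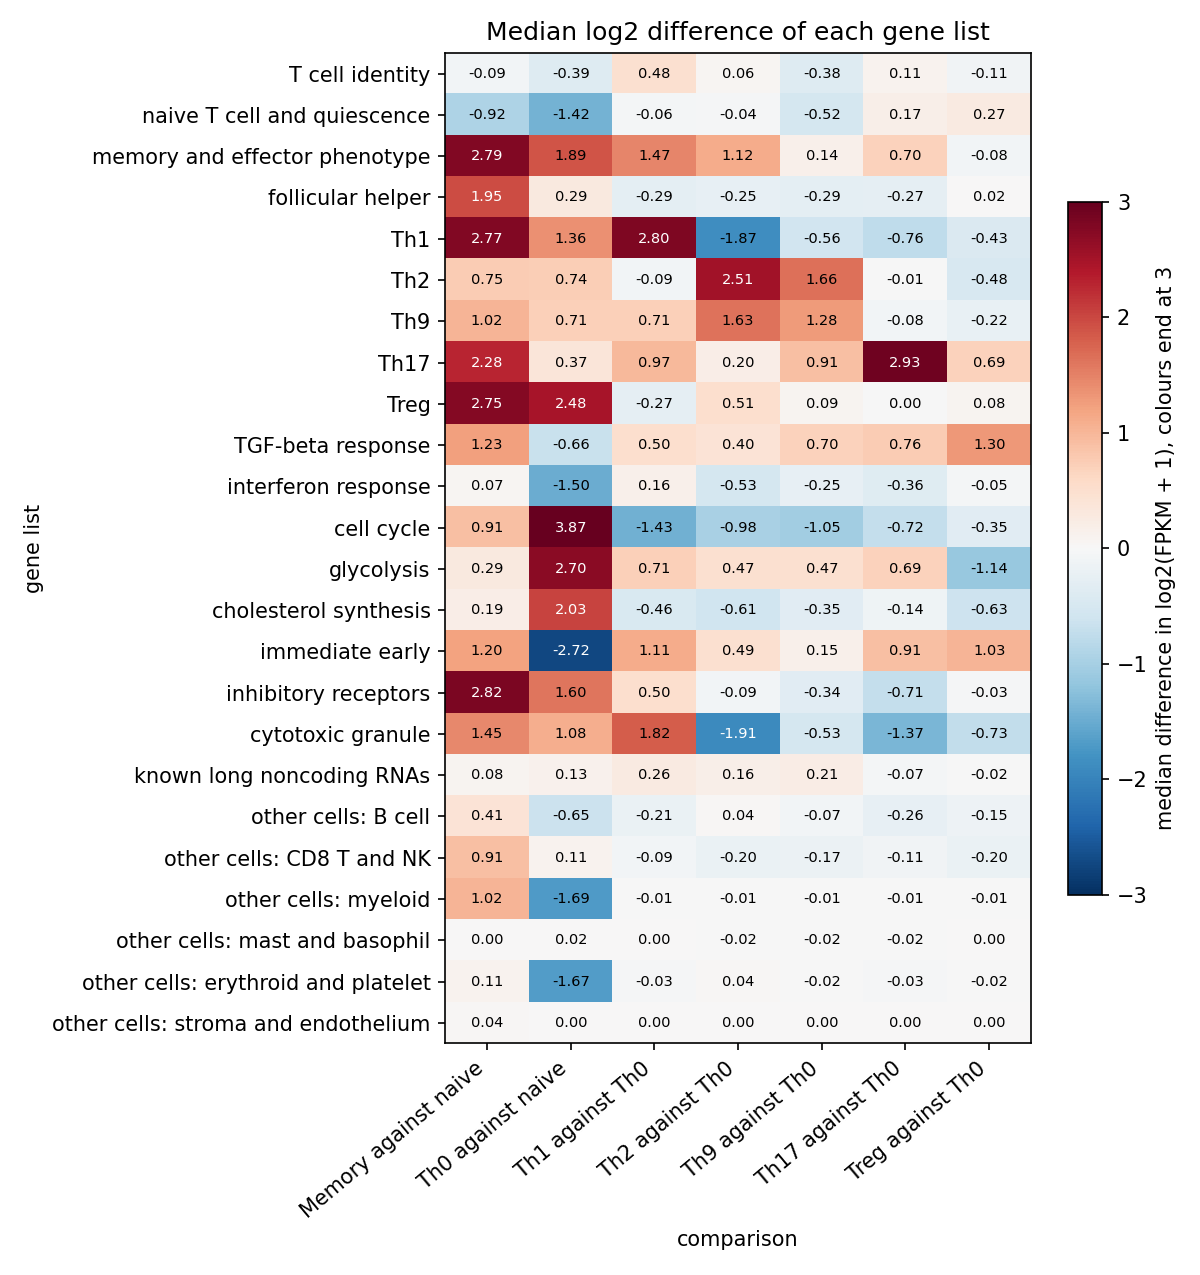
Median difference in log2(FPKM + 1) of each gene list (vertical axis) in each of the 7 comparisons (horizontal axis), with the value written in each cell and colours that end at 3 in either direction. Cell cycle is at 3.87 in Th0 against naive and between -1.43 and -0.35 in the 5 comparisons with Th0.

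Population-specific protein-coding genes were most numerous in memory, with 64, followed by 31 in Th1, 17 in naive, 13 in Th2, 7 in Th0, 7 in Th17, 5 in Treg and 3 in Th9. Klk1 (49.7 FPKM), Siglech and Ly6d (96.1 FPKM) had the largest ratios in memory, all 3 of them genes that plasmacytoid dendritic cells express, and Pink1 and Pdlim4 (57.8 FPKM) in naive. Ccl9 (131 FPKM) and Ly6g led in Th1, Ddc (64.0 FPKM) and Adamtsl3 (60.5) were among those of Th2, and Zfp28 (83.9), Ajuba (42.7) and the uncertain Grik3, which had the largest ratio, were the 3 of Th9. The collagen genes Col4a2 (13.2 FPKM) and Col4a1 (10.7) accompanied Il17f in Th17, and Dsp, which encodes desmoplakin (16.3 FPKM), led in Treg.

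Long noncoding genes of at least 1 FPKM numbered 594 in naive, 670 in memory, 567 in Th0, 700 in Th1, 629 in Th2, 628 in Th9, 660 in Th17 and 618 in Treg. Of the 1055 at that level in some library, 338 overlapped no protein-coding gene. At least 4-fold differences, higher and lower, numbered 28 and 4 in memory against naive and 30 and 40 in Th0 against naive. Against Th0 they numbered 30 and 10 in Th1, 17 and 11 in Th2, 15 and 8 in Th9, 14 and 7 in Th17, and 8 and 5 in Treg. With a pseudocount of 0.1 FPKM each of these counts was over 1.5 times as large. The list of known long noncoding RNAs did not stand apart in any comparison, with medians from -0.07 to 0.26, and Malat1 was at 188 FPKM in naive, 39.5 in Th0 and 362 in Th1.

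Several lincRNAs free of coding overlap had large differences. Gm19585 (ENSMUSG00000100150, chromosome 17, 52149289 to 52163048) was at 214 FPKM in Th2, 144 in Th1, 36.7 in Th17 and 0.933 in Th0. Gm26825 (ENSMUSG00000097554, chromosome 5, 5781530 to 5783636) was at 412 FPKM in Treg and 388 in Th17 against 5.93 in Th0. Gm26667 (ENSMUSG00000097418, chromosome 16, 84703167 to 84715245) was at 217 FPKM in Th1 and 182 in Th9 against 11.2 in Th0. Antisense genes that overlap a coding gene included Gm15655 (chromosome 8, 115705078 to 115707233, overlapping Maf), at 91.9 FPKM in Th1, 69.9 in Th17, 65.3 in Th2 and 0.421 in Th0. Gm12534 (chromosome 3, 37231333 to 37233342, in a locus joined with another noncoding gene and overlapping Il21) was at 29.5 FPKM in Th17, 26.3 in Th1 and 0.0355 in Th0. Reads of these antisense genes and their partners cannot be told apart here. Rian (chromosome 12, 109603940 to 109661716) was specific to Th0 at 13.7 FPKM, Gm16224 (chromosome 4, 135143421 to 135144285, overlapping Runx3) to Th1 at 8.63, and Gm10129 (chromosome 13, 38150477 to 38151792, overlapping Dsp) to Treg at 5.26.

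Long noncoding genes varied with the nearest protein-coding gene. Over 969 pairs with starts within 100 kb, of which 953 had a correlation, the median r across the 8 libraries was 0.471. Random coding genes matched on mean expression gave medians from -0.05 to 0.05 over 95% of 10000 draws. Over the 279 pairs without overlap of a coding gene the median was 0.416. Of 7 population-specific long noncoding genes in these pairs, 4 (57.1%) had a neighbour highest in the same library, against 9.23% for random partners. These were 1810006J02Rik with Pam in naive, Rian with Rtl1 in Th0, Gm10129 with Dsp in Treg and Gm16224 with Runx3 in Th1. Gm10129 and Gm16224 overlap their neighbour.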

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

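All tests in this part except those on the plasmacytoid and the rapidly induced genes were chosen after the result was seen.

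Unnamed loci with a span of their own of at least 500 bases numbered 7666 and enter no comparison above. Among them, 63 had at least 5 FPKM in some library, a signal in data outside the main measurement. Of these, 6 had FPKM + 1 at least 4 times that of the next library. The largest ratio was at chromosome 6, 41225432 to 41226835, with 74.2 FPKM in Th1 and at most 0.0752 in the other libraries. Others were at chromosome 12, 12483352 to 12492606 (27.1 FPKM in Th1, 5.60 in Th9), chromosome 7, 100677757 to 100680162 (10.5 FPKM in Th2), and chromosome 15, 96643133 to 96644256 (26.1 FPKM in memory, 5.34 in naive). Unnamed loci were not compared with the positions of T cell receptor segments, so any of the 6 may be part of one.

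Siglech and the antigen-presentation gene H2-Aa were high in memory. A complete sort for CD4 T cells would remove other cells, but the memory gate described above names only CD44 and CD62L. RNA from plasmacytoid dendritic cells is a candidate source. Over 12 further genes of these cells the median log2 difference between memory and naive was 4.011 (percentile 100), 11 were higher and 10 at least 4-fold, with Klk1 at 49.7 FPKM, Ly6d at 96.1, Pld4 at 60.8 and Spib at 33.1 in memory, while Pacsin1 was lower (17.4 against 28.0) and 3 of the 12 reached 1 FPKM in a cultured library. Macrophage and erythroid markers, 10 in all, were present in both sorts, such as C1qa (8.77 FPKM in naive, 12.3 in memory) and Hbb-bs (13.4 and 15.6). Their median difference was only 0.06884, so these markers show no larger carry-over of all lymph node cells alike into memory. All of them except C1qc belong to lists already compared above, so this value largely restates known results and is no separate test. The low depth of naive is argued against, since the memory level of Siglech would give 403.8 fragments there, where about 4.33 were estimated. As a set, the 12 plasmacytoid genes were higher in memory, which RNA from plasmacytoid dendritic cells predicts. All of them except Tcf4, Pacsin1 and Cox6a2 stayed under 1 FPKM in every cultured T cell library. Cultured cells are not memory cells, so expression by memory T cells themselves was not tested and stays open. The 302 protein-coding genes higher in memory and its 64 specific ones may therefore include genes of other cells. The CD8 T and NK list was also higher in memory (median 0.91, 7 of 7 genes), so carry-over of other particular cells stays open.

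The 4 libraries sorted on a cytokine reporter (Th1, Th2, Th9 and Th17) differed from Th0 and Treg in the cell cycle list, with a median difference of -0.7559 between the mean log2 values and 20 of 21 genes lower (percentile 0). The same list was already lower in each of the 4 against Th0, so this value restates that result, and whether fewer cells were cycling stays open. A second stimulation before that sort could also set these libraries apart, but 12 rapidly induced genes had a median difference of 0.2742 (percentile 94.64, 7 of 12 higher), between the bounds set beforehand, so this test left it open. Lif (11.7 to 41.2 FPKM against 8.55 in Th0 and 2.85 in Treg) was higher in all 4, and Nr4a3 (4.73 to 63.6 against 78.9 and 217) lower. Polarizing cytokines and sort changed together, so a biological difference between the conditions stays open.

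Some abundant genes were listed at exactly 0 in 1 or more libraries. Among 704 protein-coding loci with a median of at least 100 FPKM over those of the 7 deeper libraries where they were above 0, 4 were listed at 0 in any of the 7: Gapdh and Eef2 in Th1 and Th9, Eef1a1 in the 6 cultured libraries, and Grik3 in all but Th9. A failed estimate at loci with very many fragments may be the cause. The predicted fragments of the 4 loci had a median percentile of 99.64 among the 704, and none was under 98.4. Grik3 entered the 704, and got its percentile, through its uncertain Th9 value alone, so it is no support for this cause. Further, 4 loci are under the minimum of 5, which was set after 2 of them were seen, so a failed estimate stays open. For Gapdh, the other 11 glycolysis genes were higher than in Th0 by a median of 0.738 in Th1 and 0.54 in Th9. The rest of its pathway was thus not absent there. The median of the glycolysis list was already known to be higher in both, so this restates that result and is no separate test. A median over all 7 libraries, used first, left 2 of 702 loci because zeros lower it, and in the shallow naive library 7 of the 704 were listed at 0, for which no explanation was tested.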

How the results depend on the processing

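The alternatives that left out loci listed at 0, thinned the deeper library, left out short transcripts or used only the 6 cultured libraries were chosen after seeing the data. Of the values recomputed under an alternative, 347 list medians, 185 differences of named genes and 217 counts and other values were kept, 311, 388 and 111 moved, and 1 list median reversed. The kept counts include those of 4-fold different long noncoding genes without a minimum, which could not differ from the main counts. Counts of at least 4-fold protein-coding differences stayed within 1.5 times under both rescalings, a pseudocount of 0.1 FPKM, other FPKM minimums, removal of loci listed at 0 or of short transcripts, and thinning to the naive depth. No paired analysis was possible because each population had 1 library, and leaving out each replicate was not run for the same reason. Alternatives that gave no value were the next highest cultured library for naive and memory, which are not cultured, and list medians with no member left at 1 FPKM, in the mast cell and basophil list in every comparison, the erythroid list against Th0 and the B cell list in Treg against Th0. Depth limits the naive library most, as the error and floor values above show. Unless stated, the cause was not tested.

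With a pseudocount of 5 FPKM, higher and lower protein-coding genes numbered 116 and 10 in memory against naive, 296 and 146 in Th0 against naive, 143 and 40 in Th1, 152 and 53 in Th2, 93 and 49 in Th9, 85 and 29 in Th17, and 16 and 19 in Treg, since a larger pseudocount shrinks every ratio. Against the median of the other 5 cultured libraries they numbered 128 and 33 in Th1, 148 and 59 in Th2, 89 and 44 in Th9, 59 and 33 in Th17, and 85 and 185 in Treg. With a pseudocount of 0.1 FPKM, higher and lower long noncoding genes numbered 108 and 36 in memory against naive, 103 and 114 in Th0 against naive, 82 and 23 in Th1, 55 and 34 in Th2, 39 and 34 in Th9, 51 and 18 in Th17, and 22 and 14 in Treg, since a smaller pseudocount widens ratios of low genes. Among those with no overlap of a protein-coding gene, a smaller set by construction, they numbered 15 and 1 in memory against naive, 12 and 19 in Th0 against naive and 3 and 5 in Th9. The higher ones there numbered 13 in Th1, 4 in Th2, 5 in Th17 and 1 in Treg, where 3 were lower.

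At 2 times the next library, population-specific protein-coding genes numbered 567 in all, with 123 in naive, 181 in memory, 40 in Th0, 81 in Th1, 70 in Th2, 14 in Th9, 33 in Th17 and 25 in Treg. Long noncoding ones numbered 56, with 24 in naive, 12 in memory, 3 in Th0, 10 in Th1, 4 in Th2, 1 in Th17 and 2 in Treg. At 8 times, protein-coding ones numbered 42, with 2 in naive, 23 in memory, 2 in Th0, 7 in Th1, 4 in Th2, 2 in Th17 and 0 in Treg, and long noncoding ones 3, with 1 in naive and 0 in Th0, Th1, Th2 and Treg. A lower or higher ratio widens or narrows the set by construction. With a minimum of 10 FPKM, memory had 42 protein-coding ones, Th0 had 4 and Treg 3, and Th1 and Treg had 0 long noncoding ones. Against the next highest of the 6 cultured libraries there were 97 protein-coding ones, which leaves out naive and memory, with 12 in Th0 and 9 in Treg, and 5 long noncoding ones, with 2 in Th1. Without loci listed at 0 in the deeper libraries, long noncoding ones numbered 5, with 1 in naive, 1 in memory and 0 in Th2.

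Long noncoding genes of at least 0.5 FPKM numbered 869 in Th0, 1002 in Th17 and 941 in Treg. At 5 FPKM they numbered 217 in naive, 213 in memory, 195 in Th0, 219 in Th1, 205 in Th2, 206 in Th9, 208 in Th17 and 204 in Treg, and 348 in some library. The median similarity of libraries was 0.9524 by Spearman correlation and 0.8537 over genes of at least 5 FPKM. The median correlation of long noncoding genes with the nearest coding gene was 0.4161 without overlap of a coding gene, 0.5751 in only the 6 cultured libraries and 0.5415 with starts within 10 kb. The interferon response list in Th17 against Th0 had a median of 0.0414 over members of at least 1 FPKM, against -0.36 over all.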

Other observations

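No test was run in this part, and the genes in it were chosen after their values were seen.

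All of the rapidly induced genes except Il3 and Crtam were higher in memory than in naive. Il3 (0.604 against 0.690 FPKM) and Crtam (2.05 against 3.27) were lower. The Il3 level in naive was close to the 0.523 FPKM that 3 fragments give there at 2 kb. Csf2 was at 0.853 FPKM in memory, listed at 0 in naive and at 2.09 in Th0. Tnf was at 190 FPKM in memory against 27.6 in naive and 9.37 in Th0, Lif at 46.6 against 5.30 and 8.55, and Il2 at 21.1 against 0.353 and 1.36. Nr4a3 was at 580 FPKM in memory, 182 in naive and 217 in Treg, and at most 78.9 in the other cultured libraries. The chemokine receptor gene Ccr9 was at 63.0 FPKM in memory and at most 2.60 elsewhere, and which cells gave this signal was not tested. Nrgn, among the largest negative differences of Th1 against Th0, was at 81.8 FPKM in Th2 and 68.9 in Treg.

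Xist, expressed from the inactive X chromosome, was at 55.5 to 154 FPKM in all 8 libraries, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in all 8.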
